A study of Mus musculus with 11 samples.

How the data were processed

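Lung tissue of 129S1 mice was profiled on 11 Affymetrix mouse gene arrays, 1 array per sample. Per the labels' protocols, mice were gavaged 5 days a week for 2 months with aspirin at 4 mg per kg, triptolide at 1 mg per kg, or both. Total RNA was extracted with a Qiagen RNeasy kit, and biotinylated cDNA was prepared from 100 ng of it. Groups and replicate numbers were taken from the sample titles, which give 2 untreated controls, 3 aspirin, 3 triptolide and 3 combination samples. The treatment protocol lists a PBS buffer group where the titles say untreated control, and the labels do not settle whether the controls were gavaged with buffer. The labels give no sex, age or collection time for any animal. They do not say that replicates of a group are separate animals either, so every p-value here measures only the spread between these samples.

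The deposited table holds 1 log2 expression value per row and array, over 35556 rows. RMA, a background correction and summary method for Affymetrix probes, and Partek, an analysis program, are named in the submitters' processing notes. Their versions, roles and settings, any filter and the array's build are not given in the sources used here. Array medians ran from 8.135 to 8.254, and the sorted values of the arrays differed by up to 0.29, so the deposited values do not share 1 common distribution. That does not show whether the probes were normalized before they were summarized. No detection call or background level comes with the values, and the number of arrays limits the precision.

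Rows were named through GEO's platform annotation, which listed 23410 of the rows. Of these, 21789 carried 1 gene symbol and 1621 carried several. The other 12146 rows were unnamed here. Rows with several symbols were not tested. Where 999 genes had more than 1 row, the row with the highest mean over all arrays stood for the gene, which left 19938 genes. Symbols were compared with the GRCm38.p6 RefSeq gene table through their gene identifiers, and 0 needed updating. That table was used only for names and for telling autosomal genes from those on the sex chromosomes. Ptgs1, Nfkb1, Hspa1b and Ddx3y were not analysed here.

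Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 11 arrays and all 4 groups, with no covariate and no filter on low values. The fit had 7 residual degrees of freedom, and moderation added 3.68 prior degrees of freedom. All 6 pairwise contrasts were taken, with the interaction of the drugs (combination minus aspirin minus triptolide plus control) and the mean of the treated groups minus control. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes, and a gene passed at an adjusted p under 0.05.

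Gene lists were written from general knowledge and cover inflammatory, stress, proliferation and metabolic pathways and the markers of lung, muscle and blood cell types. They held 655 symbols, of which 603 were matched, 4 of them through a synonym. All 37 lists had at least 5 measured members. Lists were tested with limma's camera, a test that compares a list with all other genes, at its preset correlation of 0.01 between members, and adjusted over the lists of a comparison. Camera with the correlation estimated from the residuals and fry, a rotation test of whether members move one way, were run beside it. List levels are the mean log2 value of the members on an array minus their mean over the 11 arrays. Groups, contrasts, gene lists, the rule for naming genes and the other settings were fixed before the data were examined.

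The naming rule took, for each comparison, the 12 largest rises and falls among genes that passed and whose groups did not overlap. Where fewer than 5 passed in a direction, it took the 5 genes with the smallest p in that direction, named as not having passed. Predicted genes, clones, small RNAs, olfactory, vomeronasal and taste receptors and immunoglobulin and T cell receptor segments were to be skipped; Igha and Ighm are constant regions and were kept. It added up to 4 members of each called list with the smallest p in the list's direction, and always Ptgs2, Ercc3, Rela, Hspa1a, Myc, Mki67 and sex-linked genes. Genes named outside the rule are said to have been chosen after their values were seen.

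The fit was tested on simulated data with 50 genes changed at each of 4 sizes. For the combination against control, 13 genes of log2 0.5 were recovered, 37 of 1, 49 of 2 and 50 of 4, with 5 false calls. For the combination against triptolide, 27, 47, 49 and 50 were recovered in that order, with 14 false calls. Over 20 simulated data sets for the combination against control with no change, camera made a call in 0 and fry in 2, and camera recovered a list shifted by log2 0.5 in 20 of 20 data sets. Simulated genes varied independently of each other. These runs therefore do not show how often camera calls an unchanged list whose members are correlated.

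Alternatives were each array centred on its median, quantile normalization, genes under the 30th percentile of mean expression left out, all rows tested, trend and robust moderation, no moderation, only the arrays of the groups compared, the replicate number as a block, array weights, unadjusted p with a fold of at least 1.5, joint adjustment of all list tests, and each array left out in turn. Alternatives chosen after the data were seen left out 3 arrays together, added the level of Y-linked genes as a covariate, or compared arrays of like Y-linked level. Within groups, the mean Y-linked level varied most with triptolide, at 6.55 on triptolide 1 and 9.36 and 9.08 on triptolide 2 and 3. That covariate therefore rests largely on triptolide 1, and a call it ends or turns is not thereby shown to follow sex. The comparisons against control share the same 2 control arrays, so their similarity was set beside 20 simulations of unchanged groups. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.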

Results

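Aspirin and triptolide, a diterpenoid from the thunder god vine that targets the transcription factor subunit Ercc3, were given to mice alone and together in a study of lung cancer suppression. Expression was measured in lung tissue on 11 arrays, with 2 in the untreated control group and 3 each in the aspirin, triptolide and combination groups, over 19938 genes. Values are log2 levels, and differences are given as log2 ± SE of the limma fit unless stated otherwise. Correlations between arrays across genes ran from 0.9474 to 0.9965. Combination 1 stood apart from the other arrays at 60.2 on the first principal component, which held 45.5% of the variance, while the other arrays lay between -15.0 and 6.8.

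Xist, the RNA that silences an X chromosome in females, and the Y-linked genes Eif2s3y, Uty and Kdm5d differed widely between the arrays. Xist read 11.98 and 12.07 in the control arrays, 7.0, 6.86 and 6.77 with aspirin, and 12.26, 12.80 and 12.31 with the combination. Eif2s3y, a translation initiation factor gene on the Y chromosome, read 5.29 and 5.05 in control, 9.26 to 9.48 with aspirin and 4.58 to 6.76 with the combination. The triptolide arrays were mixed, with Xist at 12.32, 9.75 and 6.61 and Eif2s3y at 6.39, 9.82 and 9.56. Usp9y, another Y-linked gene, lay between 4.79 and 5.34 on every array. Any difference between aspirin and control or between the combination and aspirin therefore coincides with a difference in these genes, while control and combination arrays are alike in them.

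**Figure D1:**
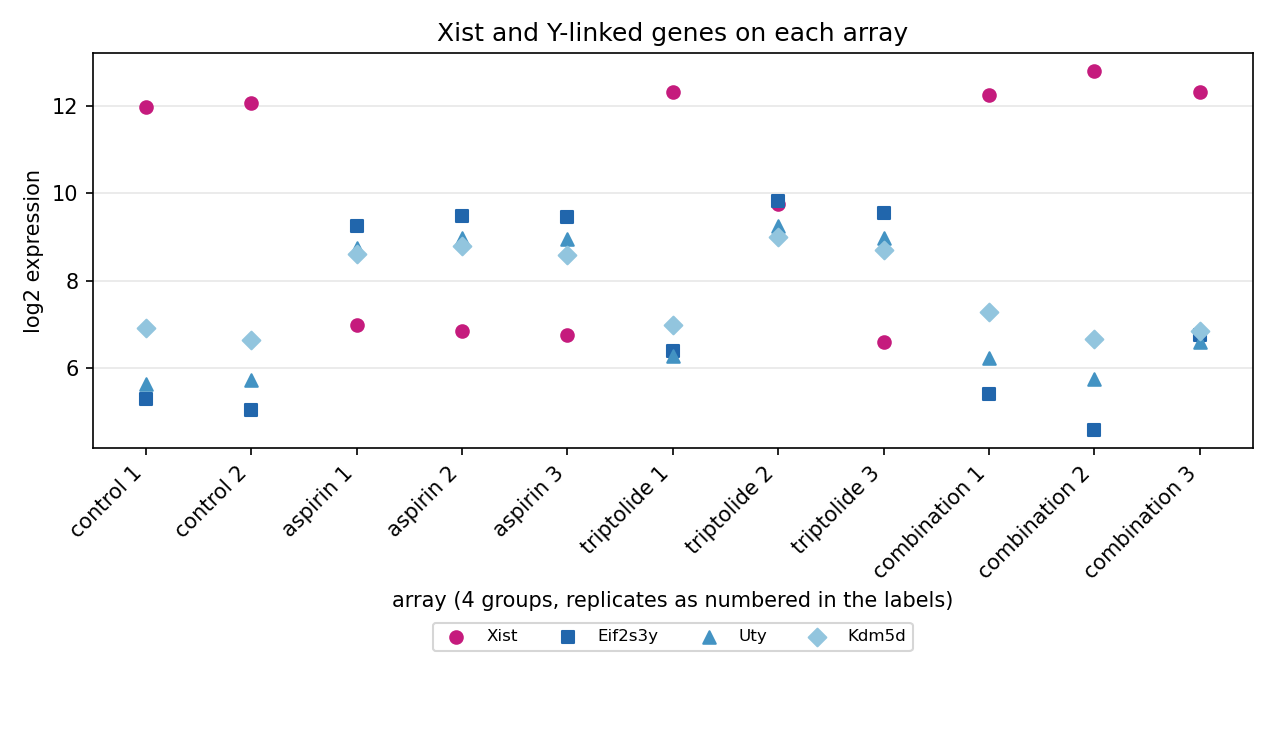
Log2 expression of Xist and of the Y-linked genes Eif2s3y, Uty and Kdm5d on each of the 11 arrays, with 1 symbol per gene. Xist is high in control, triptolide 1 and the combination, low in aspirin and triptolide 3, and at 9.75 in triptolide 2.

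The first comparison asked what aspirin alone does to lung expression. Genes of platelets and megakaryocytes, the cells of clotting and their precursors, were called higher, with all 10 measured members above control and a median difference of 0.89. Pf4, a chemokine of platelet granules, differed by 1.61 ± 0.48, Nrgn by 0.68 ± 0.21 and Clec1b, a platelet activation receptor, by 0.60 ± 0.15. Camera called this list at an adjusted p of 4.2e-15, against an adjusted p = 0.385 with an estimated correlation. Its level was 0.71 ± 0.72 (SD, n = 3) with aspirin and -0.44 ± 0.01 (SD, n = 2) in control, and aspirin 2 stood highest at 1.51. Of its members, 9 passed when adjusted over the list alone and 0 over all genes. Erythroid markers, of red cells, were called higher beside it in 7 of 8 members with a median of 0.54, and stood at -0.28, 0.80 and 0.36 on aspirin 1, 2 and 3, where the platelet list stood at 0.11, 1.51 and 0.50. Camera gave the erythroid list an adjusted p of 0.0225, and 0.732 with an estimated correlation. Without aspirin 2 its adjusted p was 0.373, and the call also ended without control 1 and without aspirin 3.

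Clock genes were called higher with aspirin, with 11 of 15 members above control. Ciart, a repressor within the clock, differed by 1.02 ± 0.28, Tef by 0.71 ± 0.22 and Per3 by 0.96 ± 0.32. The clock call had an adjusted p of 2.05e-06 by camera, and 0.705 with an estimated correlation, and 5 members passed when adjusted over the list alone. Dbp, a clock output gene, read 9.01, 9.25 and 10.77 on the 3 aspirin arrays and 8.94 and 8.80 in control. Cardiac muscle markers were also called higher, with 12 of 12 members above control and a median of 0.48. Camera gave them an adjusted p of 1.4e-07, against an adjusted p = 0.705 with an estimated correlation, and the highest aspirin array was again aspirin 2, at a list level of 0.49.

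Markers of antigen-presenting and myeloid cells were called lower with aspirin, with 12 of the 14 members of the list of monocytes, interstitial macrophages and dendritic cells below control. H2-Ab1 and H2-Aa, chains of the class II molecule that presents peptides to T cells, differed by -0.43 ± 0.14 and -0.37 ± 0.14, and Cd74, their chaperone, by -0.31 ± 0.12. The adjusted p by camera was 4.46e-05, and the adjusted p = 0.347 with an estimated correlation. Fibroblast and matrix genes lay lower in 18 of 19 members, including Mfap4 at -0.54 ± 0.20, and endothelial markers in 13 of 15, including Emcn, a vascular sialoprotein, at -0.58 ± 0.20. Camera called both, at adjusted p of 7.23e-05 and 0.000415, and lost both with an estimated correlation, where the adjusted p was 0.705 and 0.732. Heat shock genes, which encode chaperones that refold proteins, lay lower in 15 of 16 members with a median of -0.12, including Dnaja1 at -0.26 ± 0.11 and Chordc1 at -0.31 ± 0.17, at a list level of -0.27 ± 0.10 (SD, n = 3) with aspirin and -0.13 ± 0.10 (SD, n = 2) in control. Camera called them at an adjusted p of 0.000977, and 0.705 with an estimated correlation, and the call ended without control 2, at 0.206, and without aspirin 1. None of the members of these 4 lists passed when adjusted over the list alone. Neutrophil markers had all 16 members above control and a median of 1.01, with Csf3r, the receptor for granulocyte growth factor, at 1.03 ± 0.47. Camera gave an adjusted p of 3.06e-06 and 0.705 with an estimated correlation; aspirin 2 stood at a neutrophil level of 2.08 against -0.27 and -0.44 on the other aspirin arrays, and without it camera's adjusted p was 0.78.

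No single gene passed for aspirin against control. limma gave 0 genes at an adjusted p under 0.05 and 609 at an unadjusted p under 0.05, where 997 would arise by chance, and the fit without moderation also gave 0. The 5 smallest p-values among higher genes were those of Asic2, an acid-sensing channel gene, at 0.80 ± 0.13, Folh1 at 0.83 ± 0.17, Cd226, an adhesion receptor of lymphocytes and platelets, at 0.77 ± 0.17, and the Y-linked Eif2s3y and Uty at 4.23 ± 0.88 and 3.22 ± 0.68. Among lower genes they were Lpar4 at -0.54 ± 0.10, Vamp7 at -0.87 ± 0.16, Mgl2, a lectin of macrophages and dendritic cells, at -0.90 ± 0.17, Slc5a12 at -0.64 ± 0.13 and Ifi203 at -0.52 ± 0.10, all with a limma adjusted p of 1. Eif2s3y did not pass although it read 5.29 and 5.05 in control and 9.26 to 9.48 with aspirin. The fit pools the spread of all 4 groups, and Eif2s3y ran from 6.39 to 9.82 within triptolide. The count of 0 therefore does not show that no gene differs. In 5193 genes, 26% of those tested, the aspirin and control groups did not overlap, where 3 arrays against 2 give 20% by chance. Camera called 19 lists, 8 higher and 11 lower, of which 0 held with an estimated correlation or by fry. With the Y-linked level as a covariate, chosen after the data were seen, 7 of the 19 were kept, and the clock, cardiac, monocyte, fibroblast, heat shock, neutrophil and erythroid lists were not. This covariate rests largely on triptolide 1. Array weights also ended the monocyte and neutrophil calls. Without triptolide 1, limma gave 4 genes.

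Triptolide against control asked what the second drug does alone. Endothelial markers were called lower, with all 15 members below control and a median of -0.37. Plvap, which forms the diaphragms of capillary pores, differed by -0.43 ± 0.12, Ednrb, an endothelin receptor, by -0.55 ± 0.18 and Tek, the angiopoietin receptor, by -0.50 ± 0.16. The list had an adjusted p of 7.81e-14 by camera, and the adjusted p = 0.41 with an estimated correlation, and 6 members passed when adjusted over the list alone. The endothelial level was -0.01 ± 0.18 (SD, n = 3) with triptolide and 0.38 ± 0.07 (SD, n = 2) in control. Gja4, a connexin of arterial endothelium, and Apln, a peptide made by endothelial tip cells, differed by -0.74 ± 0.13 and -0.69 ± 0.16, and neither passed the test of single genes.

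Heat shock genes were called higher with triptolide, with 16 of 16 members above control and a median of 0.24. Hsph1 differed by 0.68 ± 0.18, Hspa8 by 0.29 ± 0.09, Chordc1 by 0.47 ± 0.17 and the inducible Hspa1a by 0.68 ± 0.25. Camera gave an adjusted p of 9.54e-13 and, with an estimated correlation, an adjusted p = 0.143, and 0 members passed when adjusted over the list alone. Genes induced by glucocorticoids were called higher in 12 of 12 members, among them Per1 at 0.88 ± 0.28, the metallothionein Mt2 at 0.89 ± 0.31 and Mt1 at 0.52 ± 0.19. The clock list was called higher too, with Ciart at 0.79 ± 0.28. Camera's adjusted p was 2.85e-09 for the glucocorticoid list and 7.03e-06 for the clock list, with adjusted p = 0.41 and 0.527 with an estimated correlation. The STAT3 and acute phase list was led by Cebpd, a transcription factor induced in the acute phase, at 0.96 ± 0.20, and by the protease inhibitor Serpina3n at 0.48 ± 0.19. Camera called it at an adjusted p of 0.000265, and the adjusted p = 0.654 with an estimated correlation.

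Cardiac muscle markers had 12 of 12 members above control with triptolide, and triptolide 3 carried the difference, at a list level of 0.90 against -0.12 and -0.25 on the other triptolide arrays. Camera gave an adjusted p of 1.53e-07, and 0.654 with an estimated correlation. B and plasma cell markers were called higher in 15 of 18 members, with Jchain, which joins secreted antibodies, at 0.89 ± 0.37. The adjusted p by camera was 0.00188, and 0.77 with an estimated correlation. Triptolide 1 stood at a B cell level of 0.38 against -0.29 and -0.22 on the other triptolide arrays, and without it camera's adjusted p was 0.644. The B cell call ended with array weights too, and the cardiac call with the Y-linked level as a covariate and within arrays of like Y-linked level.

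For triptolide against control limma again gave 0 genes at an adjusted p under 0.05, with 561 at an unadjusted p under 0.05 where chance gives 997, and the fit without moderation gave 0. The smallest limma adjusted p, 0.716, belonged to Gja4 and to Slc5a12 at -0.73 ± 0.13; Lpar4 at -0.51 ± 0.10 and Sema3g, an endothelial semaphorin, at -0.44 ± 0.10 came with it. Higher genes with the smallest p were Cebpd, Asic2 at 0.50 ± 0.13, Ahsa2, an Hsp90 co-chaperone, at 0.42 ± 0.11, Eif2s3y at 3.42 ± 0.88 and Folh1 at 0.66 ± 0.17. Groups did not overlap in 4626 genes, 23.2% against 20% by chance. Camera called 15 lists, 12 higher and 3 lower, and 0 held with an estimated correlation or by fry. The number of called lists fell to 8 without control 1 and was 23 without control 2, and without triptolide 1 limma gave 3 genes. The Y-linked covariate ended the clock call.

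Together the drugs were set against control to ask what the combination does. Endothelial markers lay below control in 15 of 15 members, with a median of -0.78. Cdh5, the cadherin of endothelial junctions, differed by -0.89 ± 0.14, Plvap by -0.76 ± 0.12, Ednrb by -1.04 ± 0.18 and Tek by -0.95 ± 0.16. Camera called the list lower at an adjusted p of 7.35e-18, and the adjusted p = 0.426 with an estimated correlation, while fry gave an adjusted p of 0.0463. All 15 members passed when adjusted over the list alone and 0 over all genes. The list level was -0.41 ± 0.24 (SD, n = 3), and -0.67 on combination 1. Pdgfrb, the growth factor receptor of pericytes and fibroblasts, differed by -0.98 ± 0.18, and Edil3 and Rasgrp3 by -1.41 ± 0.21 and -1.07 ± 0.16.

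Markers of alveolar type 1 cells, the flat cells of gas exchange, were called lower in 11 of 11 members, with Akap5 at -1.01 ± 0.22, Clic5 at -0.65 ± 0.16 and the water channel Aqp5 at -0.69 ± 0.18. By camera the adjusted p was 5e-09, against an adjusted p = 0.628 with an estimated correlation, and 10 members passed when adjusted over the list alone. The 3 combination arrays read -0.83, -0.44 and -0.07, and the control arrays 0.19 and 0.18. Type 2 markers, of the surfactant-making cells, lay lower in 14 of 15 members, with Lyz1 at -0.90 ± 0.22, and camera's adjusted p was 4.01e-05 and 0.694 with an estimated correlation. The type 2 level was lowest in combination 1, at a level of -0.76 against -0.07 and -0.03 on the other combination arrays and 0.09 and 0.25 in control. The list of MAPK output genes and EGFR ligands was lower in 16 of 17, with the ligand Hbegf at -0.72 ± 0.16, Etv5, a transcription factor induced by the pathway, at -0.82 ± 0.20 and Spry1, its feedback inhibitor, at -0.68 ± 0.17. Its adjusted p by camera was 0.000225, and 0.681 with an estimated correlation, and 5 members passed when adjusted over the list alone. The MAPK level was -0.41, -0.19 and -0.07 on combination 1, 2 and 3, and 0.09 and 0.12 in control. Without combination 1 the call held, at a camera adjusted p of 0.00541.

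B and plasma cell markers were called higher with the combination, in 17 of 18 members with a median of 0.83. Antibody heavy chain genes Ighm and Igha differed by 1.65 ± 0.44 and 1.5 ± 0.28, Jchain by 1.32 ± 0.37, the plasma cell chaperone Mzb1 by 0.90 ± 0.21 and Derl3 by 0.86 ± 0.13. The adjusted p was 7.52e-10 by camera and 0.628 with an estimated correlation, and 6 members passed when adjusted over the list alone. On the combination arrays the list stood at 0.96, 0.47 and 0.07, the first being combination 1. Heat shock genes were called higher in 14 of 16, with Hsph1 at 1.11 ± 0.18 and Stip1, an Hsp90 co-chaperone, at 0.49 ± 0.13. Camera gave an adjusted p of 7.56e-07, and the adjusted p = 0.426 with an estimated correlation, and 5 members passed when adjusted over the list alone. The list of club and secretory cells went both ways, with 9 of 15 members above control, a median of 0.15 and 0 members passing when adjusted over the list alone. Among the members above control were Reg3g, an antimicrobial lectin, at 2.63 ± 0.88, the mucin Muc5b at 1.37 ± 0.60 and Agr2, which folds mucins, at 1.16 ± 0.49. That list's adjusted p was 0.0335 by camera and 0.694 with an estimated correlation, and without combination 2 it was 0.364. The call also ended without control 1 and without combination 3.

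Combination 1 alone set 2 further calls. Its cell cycle level was 2.50, against -0.12 and -0.36 on the other combination arrays and -0.26 and -0.23 in control, and its erythroid level was 2.85 against -0.48 and -0.69. Camera called both lists higher, at adjusted p of 1.27e-06 and 0.0447, and both calls were lost without that array, with adjusted p of 0.758 and 0.947, and with an estimated correlation, at 0.694 and 0.79. Array weights ended both calls as well, and the erythroid call held in 4 of the 11 fits that left out 1 array. Mki67, a marker of dividing cells, differed by 1.45 ± 0.96 in the combination, and it did not pass.

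**Figure D2:**
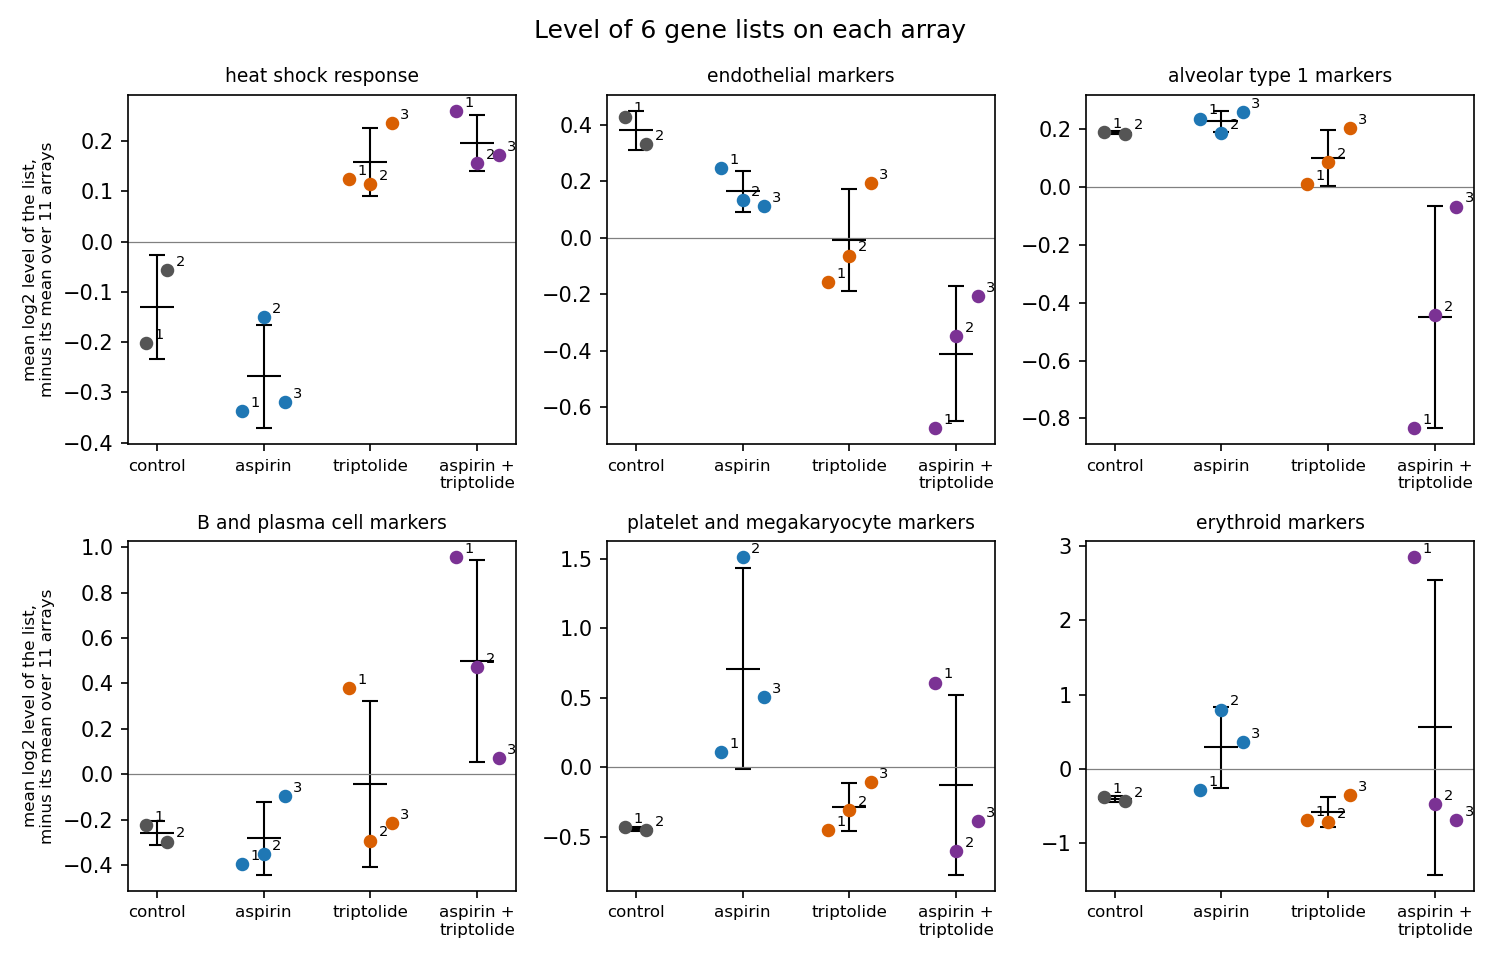
Level of 6 gene lists on each array, as the mean log2 value of the members minus their mean over the 11 arrays. Dots are arrays with their replicate numbers, and bars are group means with SD (n = 2 in control and 3 in the other groups). Endothelial levels are lowest on the combination arrays, at -0.67, -0.35 and -0.21, and the erythroid level of combination 1 is 2.85.

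No gene of the combination against control passed, although the smallest limma adjusted p was 0.0567 and 294 genes lay under 0.1. limma gave 2795 genes at an unadjusted p under 0.05, of which 680 were higher and 2115 lower, where chance gives 997; the fit without moderation gave 0 at an adjusted p under 0.05. Among the genes with the smallest p were Lpar4 at -0.76 ± 0.10, Tekt5 at -0.74 ± 0.09, Gja4 at -0.86 ± 0.13, Myb, a transcription factor of blood-forming cells, at 0.78 ± 0.13 and the iron transporter Slc11a2 at 0.47 ± 0.09. Groups did not overlap in 6930 genes, 34.8% against 20% by chance. Camera called 17 lists, 10 higher and 7 lower, and 0 held with an estimated correlation. Without combination 3, limma gave 896 genes at an adjusted p under 0.05, without triptolide 1 it gave 11, without combination 1 it gave 1, and without combination 1, aspirin 2 and triptolide 2 together, a setting chosen after the data were seen, it gave 331. The planned fit with the replicate number as a block gave 152, 9 higher and 143 lower, and whether the numbers pair the samples is not settled. With each array centred on its median, 307 genes were higher and 3332 lower at an unadjusted p under 0.05, so the split between directions moved with the centring.

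What triptolide adds to aspirin was read from the combination against aspirin. Heat shock genes were called higher in 14 of 16 members, with a median of 0.50. Hsph1 differed by 1.23 ± 0.16, Dnaja1 by 0.50 ± 0.10 and Stip1 by 0.61 ± 0.12. Camera gave an adjusted p of 1.4e-14 and, with an estimated correlation, an adjusted p = 0.0994, and fry gave 0.00686. When adjusted over the list alone, 14 members passed. The heat shock level was 0.20 ± 0.06 (SD, n = 3) in the combination and -0.27 ± 0.10 (SD, n = 3) with aspirin. The list of the unfolded protein and integrated stress response was called higher in 14 of 17 members with a median of 0.08, at a camera adjusted p of 0.000284 and 0.234 with an estimated correlation, and 5 members passed when adjusted over the list alone. Its members with the smallest p included Sdf2l1 at 0.60 ± 0.12, Creld2 at 0.44 ± 0.10 and Pdia4 at 0.44 ± 0.10, which encode proteins of the endoplasmic reticulum.

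Endothelial and alveolar type 1 markers were called lower against aspirin too, in 15 of 15 and 11 of 11 members. Cdh5 differed by -0.68 ± 0.13, Pecam1, an endothelial adhesion molecule, by -0.58 ± 0.11, Akap5 by -1.06 ± 0.20 and Hopx by -0.62 ± 0.15. Camera's adjusted p was 5.03e-16 for the endothelial list and 5.4e-13 for the type 1 list, and 0.234 for each with an estimated correlation; fry gave 0.0378 for the endothelial list. Adjusted over the list alone, 14 endothelial and 11 type 1 members passed. B and plasma cell markers lay higher in 18 of 18 members, with Igha at 1.62 ± 0.25, the B cell surface marker Ms4a1 at 1.70 ± 0.46 and Irf4, a plasma cell transcription factor, at 0.77 ± 0.13. Camera's adjusted p was 1.86e-13 for these, and 0.234 with an estimated correlation. The Y-linked level as a covariate ended the B cell call.

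Complement genes C1qa, C1qb and C1qc of tissue macrophages differed by 0.37 ± 0.11, 0.61 ± 0.18 and 0.56 ± 0.17 between the combination and aspirin. They belong to the list of monocytes, interstitial macrophages and dendritic cells, which camera called higher at an adjusted p of 9.83e-05, and 0.232 with an estimated correlation, while fry gave 0.0378, and array weights ended the call. Platelet genes were lower in 10 of 10 members, with Pf4 at -1.05 ± 0.43 and Clec1b at -0.68 ± 0.13, next to the aspirin 2 level of 1.51. The platelet list's adjusted p was 8.68e-06 by camera and 0.591 with an estimated correlation. Xenobiotic enzymes were lower in 15 of 17, with Cyp4b1 at -0.67 ± 0.14 and Fmo1 at -0.71 ± 0.16; camera's adjusted p was 0.000284, and 0.649 with an estimated correlation, and combination 1 stood at a level of -0.54 against -0.05 and 0.09 on the other combination arrays, and the call ended without combination 1, aspirin 2 and triptolide 2 together. Cell cycle genes were called higher in 29 of 29 members, at a camera adjusted p of 1.19e-09 and 0.665 with an estimated correlation, with the level of 2.50 on combination 1.

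limma gave 0 genes at an adjusted p under 0.05 for the combination against aspirin, 45 under 0.1 and 2322 at an unadjusted p under 0.05, with 683 higher and 1639 lower; the fit without moderation gave 0. The smallest adjusted p, 0.0643, was shared by Hsph1, Tekt5 at -0.72 ± 0.08 and Ifit3, an interferon-induced gene, at -0.74 ± 0.10 (limma). Asic2 differed by -0.78 ± 0.11, Smad6, an inhibitor of BMP signalling, by -0.71 ± 0.10, Stmn2, a neuronal tubulin regulator, by -1.02 ± 0.15 and Hepacam2 by 0.78 ± 0.13. In 3055 genes, 15.3%, the groups did not overlap, where 3 arrays against 3 give 10% by chance. Camera called 15 lists, 7 higher and 8 lower, and 0 held with an estimated correlation. Without combination 3, limma gave 704 genes, without triptolide 1 it gave 11 and without triptolide 3 it gave 1, and camera called 24 lists without aspirin 2.

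The converse question, what aspirin adds to triptolide, was read from the combination against triptolide. Alveolar markers were called lower for both cell types, in 11 of 11 members for type 1 and 14 of 15 for type 2. Aqp5 differed by -0.67 ± 0.16, Gprc5a by -0.76 ± 0.21 and Hopx by -0.52 ± 0.15 among the former, and the lung chemokine Cxcl15 by -0.73 ± 0.24 and the protease Napsa, which processes surfactant protein B, by -0.62 ± 0.19 among the latter. By camera the adjusted p was 1.85e-08 and 1.55e-07, and 0.748 for each with an estimated correlation. Adjusted over the list alone, 11 and 10 members passed. Combination 1 had the lowest levels of both lists, at -0.83 and -0.76.

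MAPK output genes and EGFR ligands were called lower against triptolide in 15 of 17 members, with Etv5 at -0.77 ± 0.18, the phosphatase Dusp6 at -0.69 ± 0.17, Spry1 at -0.53 ± 0.15 and Spred2 at -0.37 ± 0.11. Their adjusted p by camera was 7.43e-07, and the adjusted p = 0.748 with an estimated correlation, and 8 members passed when adjusted over the list alone. Their level was 0.42 on triptolide 2, and no higher than 0.12 on the other triptolide arrays. On combination 1, 2 and 3 it was -0.41, -0.19 and -0.07, and the call held without combination 1, at a camera adjusted p of 1.32e-05. Endothelial markers were lower in 15 of 15, with Esam at -0.61 ± 0.14 and Cdh5 at -0.49 ± 0.13, and mesothelial markers, of the pleural lining, in 8 of 8, with Upk3b at -1.19 ± 0.34. Camera called them at adjusted p of 1.85e-08 and 0.000274, and the adjusted p = 0.748 for each with an estimated correlation. B and plasma cell markers lay higher in 17 of 18, at a camera adjusted p of 8.28e-07 and 0.748 with an estimated correlation, and the call ended with the Y-linked covariate and within arrays of like Y-linked level. The mesothelial level was -0.77, 0.00 and -0.46 on combination 1, 2 and 3, and array weights ended that call. The cell cycle list was called higher at 1.38e-06 and lost at 0.863 with an estimated correlation (camera adjusted p), and its direction turned without combination 1. Erythroid markers were called higher in 8 of 8 members, at a camera adjusted p of 0.0187 and 0.863 with an estimated correlation, and the call ended without combination 1, at 0.509, without triptolide 1 and with array weights.

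Again 0 genes passed in limma for the combination against triptolide, where the smallest adjusted p was 0.353 and 2703 genes lay at an unadjusted p under 0.05, 697 higher and 2006 lower; the fit without moderation gave 0. Clca3b at 1.38 ± 0.30 and Gp2, a receptor for bacteria on mucosal cells, at 1.43 ± 0.32 were among the higher genes with the smallest p, next to Slc25a54 at 0.42 ± 0.10, Slc11a2 at 0.33 ± 0.08 and Myb at 0.45 ± 0.12. The lower ones were Tekt5 at -0.48 ± 0.08, Fgf18 at -0.48 ± 0.10, the collagen Col12a1 at -0.61 ± 0.13, Myrf at -0.46 ± 0.10 and the phosphodiesterase Pde4b at -0.61 ± 0.13. Groups did not overlap in 3568 genes, 17.9% against 10% by chance. Camera called 16 lists, 4 higher and 12 lower, and 0 held with an estimated correlation or by fry. Without combination 3, limma gave 24 genes, and without triptolide 1 it gave 4.

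Aspirin and triptolide were also compared with each other. Heat shock genes were lower with aspirin in 16 of 16 members, with a median of -0.34. Dnaja1 differed by -0.54 ± 0.10, Chordc1 by -0.78 ± 0.15, Hsph1 by -0.80 ± 0.16 and Hspa1a by -0.81 ± 0.22. Camera called the list at an adjusted p of 5.65e-22 and kept it with an estimated correlation, at an adjusted p = 0.0293, and fry gave 0.0108. Of its members 10 passed when adjusted over the list alone and 0 over all genes. Levels were -0.34, -0.15 and -0.32 on the aspirin arrays and 0.12, 0.11 and 0.24 on the triptolide arrays.

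Genes of monocytes, interstitial macrophages and dendritic cells lay lower with aspirin than with triptolide in 14 of 14 members. Cd74 differed by -0.41 ± 0.11, H2-Aa by -0.37 ± 0.12 and H2-Eb1, another class II chain, by -0.33 ± 0.11. The list was called at an adjusted p of 6.06e-09 and kept at an adjusted p = 0.0332 with an estimated correlation, and fry gave 0.0272 (camera and fry). Over the list alone, 4 members passed. The heat shock and monocyte lists in this comparison were the only ones of the 8 comparisons to hold with an estimated correlation. Neither held so within arrays of like Y-linked level (adjusted p = 0.162 and 0.183) or without combination 1, aspirin 2 and triptolide 2 (adjusted p = 0.126 and 0.219 by camera), settings chosen after the data were seen, while at the preset correlation both stayed called in each. The triptolide arrays of like Y-linked level were triptolide 2 and 3, and Xist read 9.75 on the first and 6.61 on the second. The list of the unfolded protein and integrated stress response was lower in 16 of 17 members, with Hspa5, a chaperone of the endoplasmic reticulum, at -0.28 ± 0.09, and camera's adjusted p was 8.93e-07 and 0.0855 with an estimated correlation. Platelet genes were higher in 10 of 10, with the integrin Itgb3 at 0.95 ± 0.33 and Treml1 at 0.60 ± 0.16; camera's adjusted p was 2.29e-12, and 0.302 with an estimated correlation, beside the level of 1.51 on aspirin 2. Erythroid markers were called higher with them in 8 of 8 members, with a median of 0.70, at a camera adjusted p of 0.00933 and 0.558 with an estimated correlation. The erythroid call ended without aspirin 2, at an adjusted p of 0.217, without triptolide 1, with the Y-linked covariate and within arrays of like Y-linked level.

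Single genes did not pass between aspirin and triptolide. limma gave 0 at an adjusted p under 0.05 and 660 at an unadjusted p under 0.05, 304 higher and 356 lower, against 997 by chance, and the fit without moderation gave 0. The majority turned with the scaling, to 382 higher and 298 lower with median centring and 480 and 304 with quantile normalization. The clock repressor Cry1 at 0.50 ± 0.09, Ifit3 at 0.52 ± 0.10, Smad6 at 0.52 ± 0.10, Gja4 at 0.58 ± 0.12 and Clec1b at 0.62 ± 0.13 were the higher genes with the smallest p, and P2ry10, a lymphocyte receptor, at -0.68 ± 0.15 and Hspa8 at -0.35 ± 0.08 joined Dnaja1, Chordc1 and Hsph1 among the lower ones, all at a limma adjusted p of 0.96. Groups did not overlap in 1972 genes, 9.89%, where chance gives 10%. Camera called 24 lists, 8 higher and 16 lower, of which 2 held with an estimated correlation and 2 by fry. The neutrophil list, called higher at an adjusted p of 0.00143 by camera and 0.558 with an estimated correlation, turned lower without aspirin 2 and with array weights, and ended without triptolide 1, at an adjusted p of 0.0546. Without triptolide 1, 12 lists were called, and 12 were called when aspirin was set only against triptolide 2 and 3, the arrays of like Y-linked level, a setting chosen after the data were seen.

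**Figure D3:**
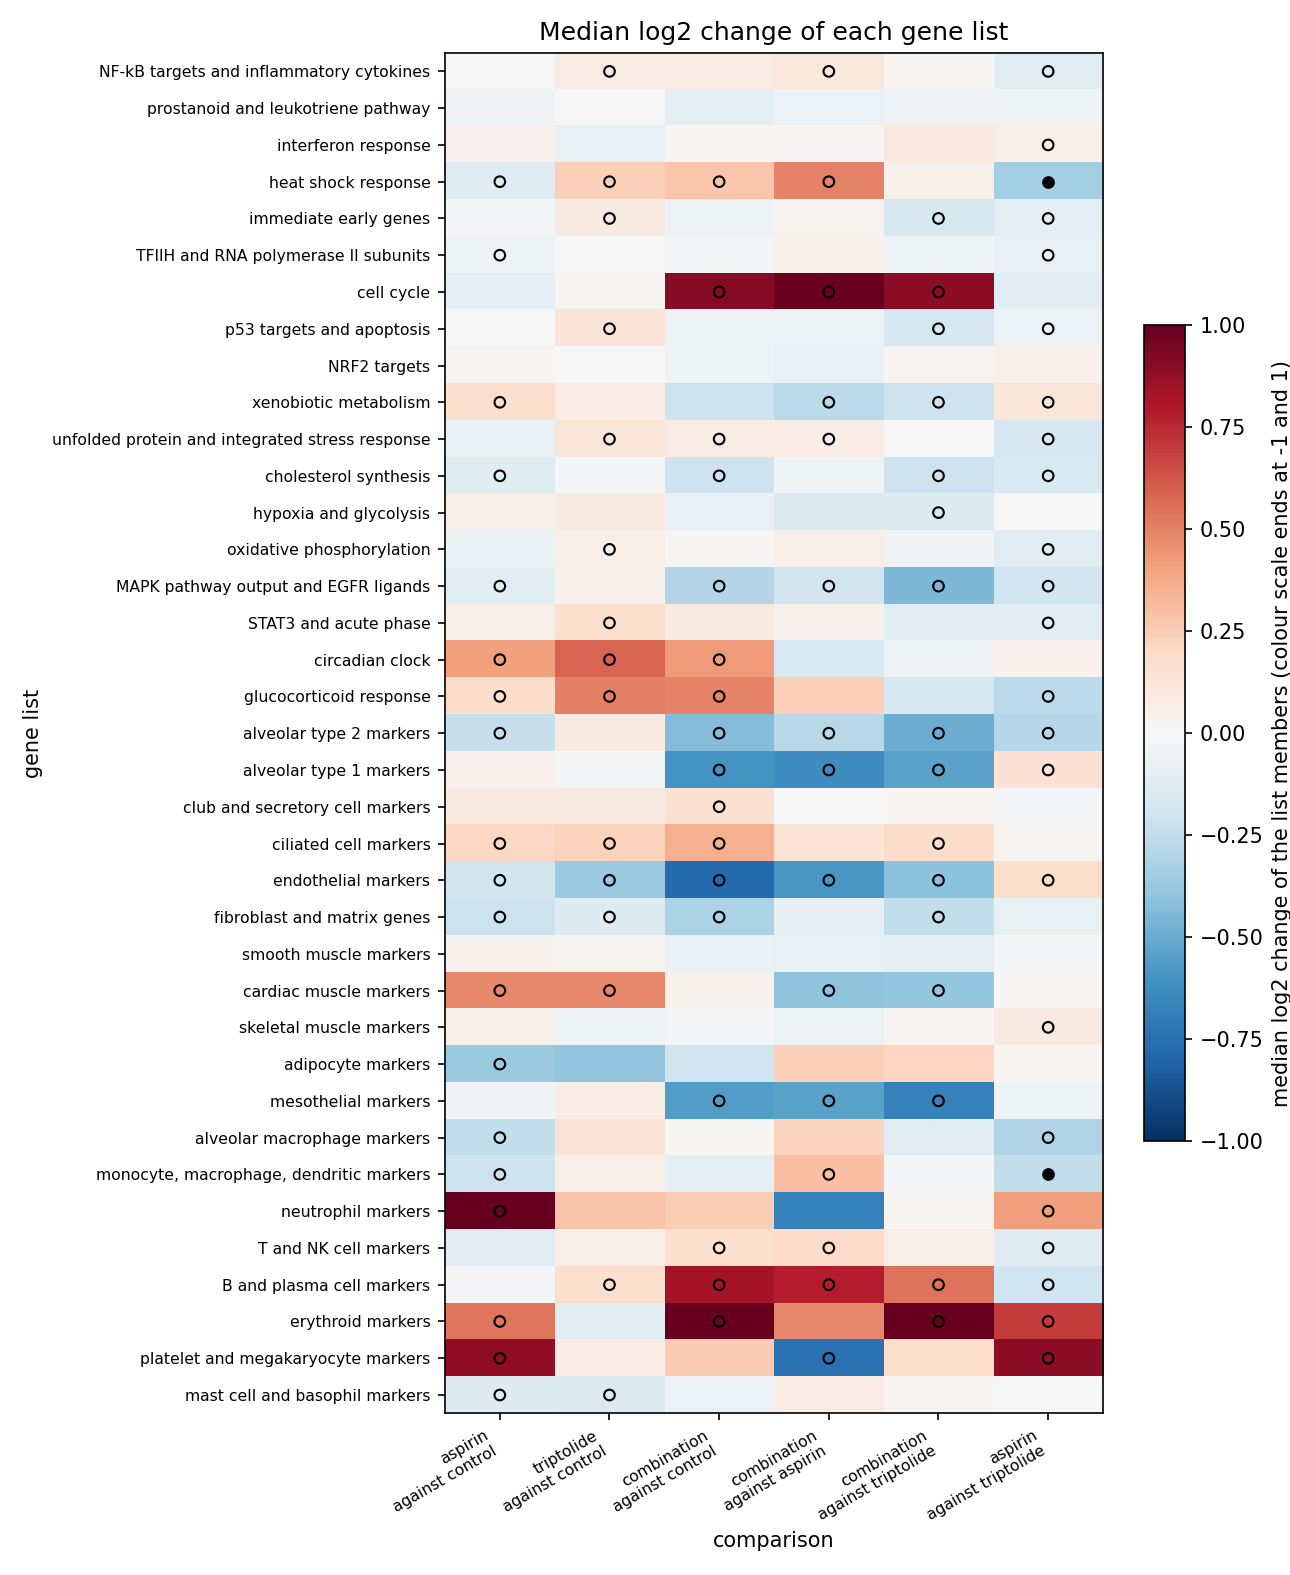
Median log2 difference of the members of each of the 37 gene lists in the 6 pairwise comparisons, by colour. Open circles mark lists called by camera at its preset correlation, and filled circles those that held with an estimated correlation, which are the heat shock and the monocyte lists in aspirin against triptolide.

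Whether the combination differs from the sum of the single drugs was tested by the interaction. Type 1 markers were lower than that sum in 11 of 11 members, with Hopx at -0.60 ± 0.22 and Aqp5 at -0.64 ± 0.24, and cardiac muscle markers in 12 of 12, with Myl4 at -1.16 ± 0.37 and Myh6 at -1.10 ± 0.39. B and plasma cell markers were higher in 18 of 18, with Ms4a1 at 1.53 ± 0.69. Camera called these lists at adjusted p of 2e-09, 1.03e-08 and 4.34e-06, and the adjusted p = 0.589 for each with an estimated correlation. The cardiac level was 0.90 on triptolide 3 against -0.12 and -0.25 on triptolide 1 and 2, and 0.49 on aspirin 2 against -0.02 and 0.07 on aspirin 1 and 3. It was -0.21, -0.18 and -0.10 on the combination arrays and -0.16 and -0.42 in control. Platelet genes were lower in 10 of 10, with Clec1b at -0.67 ± 0.20, at an adjusted p of 4.34e-06 by camera and 0.589 with an estimated correlation. limma gave 0 genes at an adjusted p under 0.05, 681 at an unadjusted p under 0.05 and a smallest adjusted p of 0.264, for Asic2 at -1.28 ± 0.17; the fit without moderation gave 0. Sex-linked genes were prominent among the smallest p-values, with Xist at 8.05 ± 1.53, the X-linked Kdm6a and Eif2s3x at 1.19 ± 0.22 and 1.07 ± 0.21, and the Y-linked Eif2s3y, Uty and Kdm5d at -7.24 ± 1.18, -5.20 ± 0.91 and -3.19 ± 0.62. Beside them stood Penk, an opioid peptide precursor, at -2.78 ± 0.54, Hepacam2 at 0.90 ± 0.20 and Adam26b at 0.80 ± 0.18. Camera called 20 lists, 6 higher and 14 lower, and 0 held with an estimated correlation or by fry. With the Y-linked level as a covariate, 5 of the 20 were kept, the type 1, cardiac and platelet calls ended, and the B cell list and Ms4a1 turned lower. That covariate rests largely on triptolide 1, so these changes do not tell sex from a property of that array. The B cell call also ended without combination 1, aspirin 2 and triptolide 2, and without triptolide 1 limma gave 6 genes.

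The mean of the 3 treated groups was set against control, a contrast that 1 regimen can move without the others. Endothelial markers were lower in 15 of 15 members with a median of -0.45, with Plvap at -0.51 ± 0.10, Emcn at -0.78 ± 0.18 and Cdh5 at -0.50 ± 0.12. Camera's adjusted p was 1.93e-17, and the adjusted p = 0.66 with an estimated correlation, and 13 members passed when adjusted over the list alone. Clock and glucocorticoid genes were higher, with Ciart at 0.89 ± 0.24 and Mt2 at 0.86 ± 0.26, at camera adjusted p of 1.25e-05 and 1.69e-05 and 0.66 for each with an estimated correlation. limma gave 0 genes at an adjusted p under 0.05 and 1186 at an unadjusted p under 0.05, with a smallest adjusted p of 0.329 for Lpar4 at -0.60 ± 0.08, followed by Slc5a12 at -0.72 ± 0.11; the fit without moderation gave 0. Tspan6 at -0.59 ± 0.10, Rasgrp3 at -0.78 ± 0.14 and Dchs1 at -0.47 ± 0.08 were the next lower genes, and Cldn34b2 at 0.33 ± 0.07, Derl3 at 0.49 ± 0.11, Myb at 0.46 ± 0.11, Fam227a at 0.44 ± 0.11 and Folh1 at 0.61 ± 0.15 the higher ones. Camera called 19 lists, 12 higher and 7 lower, and 0 held with an estimated correlation or by fry. The cell cycle list was among them, at an adjusted p of 0.0091 and 0.878 with an estimated correlation (camera), and turned lower without combination 1. Without triptolide 1, limma gave 1 gene, and the Y-linked covariate ended the clock call.

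These comparisons rest on the same 2 control arrays. Across genes, which are not independent replicates, log2 differences from control correlated at 0.54 between aspirin and triptolide, 0.43 between aspirin and the combination and 0.46 between triptolide and the combination, while simulated unchanged groups gave 0.60. The covariances of 0.0138, 0.0189 and 0.0183 lay below the simulated 0.0211, 0.0213 and 0.0213, a difference of -0.0073, -0.0025 and -0.0030. The simulations gave every group the same spread. The root mean square deviation from the group was 0.074 on each control array, below that of every treated array, and 0.306 on combination 1. The simulated values can therefore overstate what the shared controls add, and do not show whether the regimens share more than that. Genes at an unadjusted p under 0.05 in both and in the same direction numbered 176, 313 and 340, where the simulated groups gave 308.2, 312.2 and 310.3 and independent lists would share 8.7, 45.2 and 42.9. Aspirin, triptolide and the combination had 609, 561 and 2795 genes at that threshold, where chance gives 997, so these counts are not on equal terms. With a different control array for each comparison, the correlations were all positive, at 0.45 or 0.13, 0.32 or 0.22, and 0.21 or 0.36. Part of any similarity may come from the shared controls.

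Transcripts of the drugs' named targets showed no passing change, and their levels do not measure whether the drugs acted on the proteins. Ptgs2, the inducible cyclooxygenase that aspirin inhibits, differed from control by -0.18 ± 0.33 with aspirin, 0.17 ± 0.33 with triptolide and -0.36 ± 0.33 with the combination, and the first turned above 0 without control 2 and the second below 0 without control 1. Ercc3, the TFIIH helicase that triptolide binds, differed by -0.17 ± 0.08, -0.13 ± 0.08 and -0.21 ± 0.08, and Rela, an NF-kB subunit, by -0.09 ± 0.12, -0.06 ± 0.12 and -0.32 ± 0.12, the second turning above 0 without triptolide 1, without control 2 and with array weights. Myc differed by -0.20 ± 0.31, 0.33 ± 0.31 and 0.72 ± 0.31. The prostanoid and leukotriene list was called in none of the 8 comparisons, and its camera adjusted p was 0.228, 0.615 and 0.173 against control. The list of NF-kB targets and inflammatory cytokines had a median of 0.00, 0.08 and 0.08 in the same order; for aspirin its mean of -0.04 and the test's direction lay below 0 while its median did not. Camera called it higher only for triptolide, at an adjusted p of 0.0398 and 0.654 with an estimated correlation, among these 3 comparisons, and the call held in 6 of the 11 fits that left out 1 array, with an adjusted p of 0.62 without control 1. It also ended with low genes left out, with array weights and over only the arrays compared.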

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

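Every test of an explanation in this part was chosen after the result it concerns had been seen, and the test of the interaction was planned.

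In 20 gene lists the effect of aspirin with triptolide differed from its effect without it, by camera's test of the interaction at its preset correlation. Lists lower than the sum of the single drugs were, with camera's adjusted p, type 1 cells (2e-09), cardiac muscle (1.03e-08), platelets (4.34e-06), the circadian clock (0.000127), xenobiotic metabolism (0.000784), mesothelium (0.000784), type 2 cells (0.00137), MAPK output (0.00184), endothelium (0.00225), the glucocorticoid response (0.00385), hypoxia and glycolysis (0.00495), STAT3 and acute phase (0.0227), p53 targets (0.0228) and neutrophils (0.0265). Lists higher than that sum were the cell cycle (4.34e-06), B and plasma cells (4.34e-06), the heat shock response (0.00322), adipocytes (0.00997), monocytes, interstitial macrophages and dendritic cells (0.00997) and T and NK cells (0.0213). Their adjusted p was between 0.589 and 0.78 with an estimated correlation, and fry called 0. The clock list had a median of -0.49 with 14 of 15 members below 0, the adipocyte list 0.61 with 11 of 12 above 0, and the platelet list -0.74. The aspirin arrays have high Y-linked levels and the combination arrays low ones, and 5 of these 20 lists were kept with the Y-linked level as a covariate. That covariate turned the direction of the MAPK, endothelial, adipocyte, T and NK cell and B cell lists. It rests largely on triptolide 1, so it cannot tell sex from a property of that array.

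On leaving out each of the 11 arrays in turn, 8 of the 20 calls held every time, those of type 1 cells, cardiac muscle, B cells, platelets, the clock, xenobiotic metabolism, mesothelium and MAPK output, although the Y-linked covariate turned the B cell and MAPK lists. For cardiac muscle this is a weak test. Its level was 0.90 on triptolide 3 and 0.49 on aspirin 2, and leaving out 1 of these arrays kept the other. The other calls ended without at least 1 array, and the highest adjusted p by camera are given here. Without aspirin 2 it was 0.832 for neutrophils and 0.585 for STAT3, each held in 7 of the fits, 0.22 for the glucocorticoid response (9) and 0.0908 for hypoxia (10). Without combination 1 it was 0.256 for the cell cycle (10) and 0.157 for type 2 cells (10). Without triptolide 2 it was 0.769 for T and NK cells (8) and 0.15 for p53 targets (7), and without triptolide 3 it was 0.0772 for endothelium (9). Without aspirin 1 it was 0.276 for monocytes (9) and 0.136 for heat shock (9), and without control 1 it was 0.405 for adipocytes (7).

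Erythroid and cell cycle genes stood at 2.85 and 2.50 in combination 1, where the other arrays did not exceed 0.80 and -0.08. Circulating blood of the makeup seen on aspirin 2 is argued against by 10 genes of nucleated erythroid precursors, which lay 2.54 to 6.15 above aspirin 2 with a median of 3.39, while the 4 genes held by erythroid cells of any stage differed by less, with a median of 0.06, from -0.43 for Alas2 to 2.05 for Slc4a1. The bound for that test was set after its values were seen. RNA of blood-forming tissue or cells diluting that of the lung may account for it: Car1 read 13.54 against at most 7.90 elsewhere and Gata1 10.79 against at most 7.94. Members of the type 1, type 2, club and ciliated lists were also compared with the mean of combination 2 and 3. Their median differences were all negative, the highest being -0.38 for the club list. In mean level, however, the club list stood at 0.11 on combination 1, above combination 3 at 0.08 and below combination 2 at 0.89. The club list therefore does not speak for dilution against both arrays. In combination 1, 4 of 4 genes taken as markers of red pulp macrophages, which are cells of the spleen, read above every other array. The median difference of these genes from the median of the other arrays was 0.80. Hmox1 and Vcam1 among them are not particular to the spleen and also belong to the NRF2 and NF-kB lists. They read 10.38 and 10.73, against at most 10.13 and 10.37 elsewhere. The share of all genes that read highest on this array was not taken. The 4 genes of neutrophil precursors also read above every other array, with a median difference of 1.10. Whether such cells lay in the lung itself or entered with other tissue cannot be told from these values, because no array of another tissue was measured. No biological explanation was tested.

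Sex of the animals is an open explanation for what differs between aspirin and control, because Xist and the Y-linked genes part these groups completely. Across 19106 autosomal genes, the difference of triptolide 2 and 3 from triptolide 1 correlated at -0.11 with the aspirin difference, but with 1 array of low Y-linked level in that group the value excludes nothing, and sex and aspirin cannot be told apart there. It is argued against for the lower endothelial markers of the combination, where the lowest Xist level among control and combination arrays was 11.98 and the highest with aspirin 7.0. Whether the combination itself lowers these markers stays a hypothesis, found and tested on the same data: camera's call was lost with an estimated correlation (adjusted p = 0.426), while fry gave 0.0463.

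Heat shock genes were lower in every aspirin array than in every triptolide array, and against control they were called lower with aspirin (-0.27 against -0.13 in level, camera adjusted p 0.000977, and 0.705 with an estimated correlation) as well as higher with triptolide. The call with triptolide was also lost with an estimated correlation. Among arrays of low Y-linked level, the heat shock level was -0.20 and -0.06 in control. It was 0.12 on triptolide 1 and 0.26, 0.16 and 0.17 on the combination arrays, which argues against sex for the difference between these arrays. Between aspirin and triptolide sex stays open. The lower of the 2 triptolide arrays with high Y-linked levels lay 0.26 above the highest aspirin array. That array is triptolide 2, however, whose Xist of 9.75 leaves triptolide 3 as the only plain match. Time of day stays open too: aspirin 1 and aspirin 3 differed by 1.76 in the clock output gene Dbp and by 0.02 in heat shock level, where the drug groups differed by 0.43, but that rests on aspirin 3 alone, and Dbp was 8.80 to 9.25 on the other 4 arrays without triptolide and 9.44 to 10.42 on the 6 with it. Triptolide exposure, which gave levels of 0.11 to 0.26 on 6 arrays against -0.34 to -0.06 on the other 5, is a candidate explanation that stays open as well: an exact two-sided permutation test gave p = 0.00216, the smallest that 462 groupings can give, and 0.0801 after adjustment over 37 lists, which a lone list cannot better. Triptolide is known to block the induced heat shock response in cultured cells, and what differs here was not tested.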

How the results depend on the processing

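The settings without 3 arrays (combination 1, aspirin 2 and triptolide 2), with the Y-linked level as a covariate and within arrays of like Y-linked level were chosen after the data were seen, and the others were planned. The Y-linked covariate rests largely on triptolide 1. Leaving out a control leaves 1 control array, which is then assumed to vary like the other groups. The cause of the changes below was not tested, except where fewer genes or arrays were used by construction. The values carry no signal over background, so low genes have no stated limit.

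Counts of genes at an adjusted p under 0.05 were 0 in all 8 comparisons and remained 0 without moderation and over all rows. For the combination against control and against aspirin they were 66 and 1 with low genes left out, 2 and 2 after quantile normalization, and 56 and 1 with trend and robust moderation. Centring on the median gave 335 for the combination against control, 8 higher and 327 lower, and 268 of them had an adjusted p under 0.1 before. Only the arrays compared gave 4 for aspirin against control and 2 for the combination against aspirin. Array weights, which ran from 0.11 to 43.46 and so rest on few arrays, gave 2935 for aspirin, 337 for triptolide and 3838 for the combination against control, 6479 and 4959 for the combination against aspirin and triptolide, 6862 for aspirin against triptolide, 2139 for the interaction and 1423 for all treated. An unadjusted p under 0.05 with a fold of at least 1.5 gave 89, 63, 612, 367, 199, 53, 212 and 85 in that order. Without 3 arrays the counts were 331 for the combination against control, 5 against aspirin and 5 for all treated, and with the Y-linked covariate 96 for the combination against control.

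With the replicate number as a block, limma gave 152 genes for the combination against control, and 0 elsewhere. Whether the numbers pair the samples is not settled. Of 15 same-numbered pairs, 6 had deviations correlated over 0.1 (range -0.14 to 0.33), and their median was 0.08. The 30 pairs of different number had a median of -0.07, and 7 of 11 arrays correlated best with their own number.

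Leaving out each array in turn gave 0 to 4 genes for aspirin against control, 0 to 3 for triptolide, 0 to 896 for the combination, 0 to 704 for the combination against aspirin, 0 to 24 against triptolide, 0 for aspirin against triptolide, 0 to 6 for the interaction and 0 to 1 for all treated. Without combination 3 came 896, 704 and 24; without triptolide 1 came 4, 3, 6 and 1. Called lists ran from 16 to 20 for aspirin, 8 to 23 for triptolide and 12 to 19 for the combination against control, 15 to 24 and 13 to 16 for the combination against aspirin and triptolide, 12 to 26 for aspirin against triptolide, 15 to 23 for the interaction and 13 to 21 for all treated. The 8 came without control 1, the 24 without aspirin 2 and the lower 12 without triptolide 1.

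With an estimated correlation camera called 0 lists in 7 comparisons and 2 in aspirin against triptolide; fry called 1 for the combination against control, 3 for the combination against aspirin, 2 for aspirin against triptolide and 0 in the other 5. Leaving out low genes gave 10 lists for the combination against triptolide. The Y-linked covariate gave 11 for aspirin against control, 15 for aspirin against triptolide and 12 for the interaction, and arrays of like Y-linked level gave 12 for aspirin against triptolide. With the controls exchanged, the correlation was 0.13 between aspirin and triptolide and 0.22 between aspirin and the combination.

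Some list directions turned, given here with camera's unadjusted p. Array weights turned endothelial (0.987), alveolar macrophage (0.954), neutrophil (0.0241) and B cell lists (0.0631) in aspirin against triptolide and STAT3 in the interaction (0.484). Without 3 arrays these turned: glucocorticoid in aspirin against control (0.826), fibroblast in the combination against triptolide (0.961), interferon (0.965) and neutrophil (0.000262) in aspirin against triptolide, p53 (0.766), STAT3 (0.196), type 2 (0.117) and T cell (0.348) in the interaction, and cell cycle in all treated (0.144). The Y-linked covariate turned adipocyte (0.182) and alveolar macrophage (0.527) in aspirin against control, oxidative phosphorylation in triptolide against control (0.0581), MAPK (0.172), cardiac (0.702) and T cell (0.363) in the combination against aspirin, ciliated in the combination against triptolide (0.559), and MAPK (0.0143), endothelial (0.102), adipocyte (0.0934), T cell (1.67e-05) and B cell (0.0001) in the interaction. It also left Uty at 0.16 and Kdm5d at 0.22 in the interaction, which follows from its construction, and turned Ms4a1 there to -1.30. Within arrays of like Y-linked level, oxidative phosphorylation turned in triptolide against control (0.124).

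Single arrays turned 5 lists. The p of the adipocyte list in aspirin against control ran from 6.85e-07 to 0.635, turned without control 1. Cholesterol in all treated ran from 2.54e-07 to 0.906, turned without control 2. Neutrophil genes in aspirin against triptolide ran from 4.25e-11 to 0.0192, and turned at 0.0037 without aspirin 2. Cell cycle genes ran from 3.03e-12 to 0.484 in the combination against triptolide and from 4.15e-06 to 0.94 in all treated, turned without combination 1 in both. Of single genes, none of which had passed, Ptgs2 ran from -0.53 (without aspirin 2) to 0.063 (without control 2) in aspirin against control and from -0.08 (without control 1) to 0.42 (without control 2) in triptolide against control. Rela in triptolide against control ran from -0.14 (without control 1) to 0.037 (without triptolide 1), and read 0.023 with array weights.

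Scaling moved the share of higher genes at an unadjusted p under 0.05. For aspirin, triptolide and the combination against control it was 44.2%, 41.2% and 24.3% as deposited, 19%, 15.2% and 8.44% with median centring, and 29.7%, 15.5% and 19.1% with quantile normalization. For the combination against aspirin and triptolide it was 29.4% and 25.8%, then 18.1% and 15.1% with median centring, and 28.4% and 28.5%, little moved, with quantile normalization. For aspirin against triptolide and the interaction it was 46.1% and 34.8%, then 56.2% and 48.8%, and 61.2% and 54.3% with quantile normalization. For all treated it was 30.5%, 9.85% and 18.5%.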

Other observations

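The tests of other splits of the arrays were planned; the exposure test, the comparison of triptolide 1 with the combination and the genes Cxcl13, Asic2 and Penk were chosen after values had been seen.

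Cilia genes, of the cells that clear mucus, were called higher in the combination against control in 15 of 17 members, with Hydin at 0.59 ± 0.21 and Foxj1, the master regulator of cilia, at 0.44 ± 0.18. Camera's adjusted p was 4.41e-05, and 0.694 with an estimated correlation, and the list levels were 0.39 and 0.34 on combination 2 and 3 and -0.31 on combination 1. Mucous genes varied within groups: Muc5b read 11.12, 11.84 and 10.98 in the combination, 11.29 on triptolide 1 and 8.53 to 10.37 on the other arrays, and Reg3g 10.10 and 10.94 on combination 1 and 2 and 6.25 to 8.86 elsewhere. Mast cell markers were called lower with aspirin, with the protease Cpa3 at -0.93 ± 0.26, at a camera adjusted p of 0.00648 and 0.705 with an estimated correlation. Without control 1 the mast cell adjusted p was 0.336.

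Cxcl13, the chemokine that draws B cells into follicles, read 11.44, 10.80 and 11.02 in the combination and 11.14 on triptolide 1, and differed by 1.62 between the combination and control at a limma adjusted p of 0.104. Asic2 read 8.41 to 8.73 on the aspirin arrays and on triptolide 2 and 3, which have high Y-linked levels, and 7.83 to 8.09 on the other 6 arrays. Penk read 10.30 to 11.08 on the former and 8.74 to 9.64 on the latter. Triptolide 2 combined an Eif2s3y of 9.82, a Kdm5d of 9.0 and a Uty of 9.26 with a Xist of 9.75, between the levels of the other arrays, and the source of these levels was not tested.

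The departure of triptolide 1 from the other triptolide arrays correlated at 0.44, across autosomal genes, with the difference between the combination and control. Across all genes tested, triptolide 1 itself correlated at 0.9965 with combination 3, the highest of all pairs of arrays. With combination 1 and 2 it correlated at 0.9587 and 0.9932. The values were 0.9880 and 0.9927 with triptolide 2 and 3, and 0.9915 and 0.9934 with control 1 and 2. Why triptolide 1 lay closest to combination 3 was not tested. Triptolide 1 has the high Xist and low Y-linked levels of the control and combination arrays. A response to triptolide that differs between the sexes is a candidate explanation, and with 1 such array it cannot be told apart from a property of that array.

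The 6 arrays with triptolide were compared with the 5 without it, and the 6 with aspirin with the 5 without it, over 37 lists by exact two-sided permutation tests. After adjustment 0 lists passed for either drug; a lone list at the smallest p that 462 groupings can give has an adjusted p of 0.0801, so it could not pass in this design. For triptolide, the unfolded protein list gave an adjusted p of 0.0801 (unadjusted exact p = 0.00433, difference 0.16), the list of monocytes, interstitial macrophages and dendritic cells 0.0801 (unadjusted exact p = 0.00649, difference 0.16) and the endothelial list 0.1 (unadjusted exact p = 0.0108, difference -0.46). For aspirin, MAPK output was lowest in p (unadjusted exact p = 0.00866, adjusted 0.2, difference -0.28), followed by type 2 markers at a difference of -0.37.

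Splits of the 6 arrays of a comparison into 3 and 3 number 10, too few for a share under 0.05. For the combination against aspirin, 2322 genes lay at an unadjusted p under 0.05 and the highest of the other splits gave 2448, so that 2 splits gave as many. Called lists there numbered 15 and at most 24, with 9 splits giving as many. In the combination against triptolide the genes numbered 2703 and at most 2924, with 2 splits as large, and the lists 16 and at most 23, with 6. For aspirin against triptolide the genes numbered 660 and at most 2952, with 4 splits as large, and the lists 24 and at most 21, with 1. The 2952 came from aspirin 1, aspirin 3 and triptolide 1 against the rest, several times the real count, which points to a structure of the samples that was not tested further.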
